A study of Mus musculus with 8 samples.

How the data were processed

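Total RNA was taken from the whole uterus of 8 mice on day 3.5 of pseudopregnancy, 4 controls and 4 Foxa2-deleted animals, and 150 ng of each was carried through an Affymetrix whole-transcript labelling protocol with biotin, per the labels' protocols. Each uterus went onto 1 array of its own and no samples were pooled. The labels call the replicates biological and give 4 mice per genotype, so the p-values measure the spread between animals. Groups and replicate numbers were taken from the titles and genotypes in the labels.

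The values used are the authors' deposited log2 intensities, 1 per probe set and array, made with RMA, which corrects background, normalises between arrays and summarises probes in 1 procedure, per the submitters' processing notes. These notes also name limma. Versions, the genome build and the probe set annotation behind the deposited values are not given in the sources used here. The values are rounded to 2 decimals, are not centred per gene, and ran from 2.73 to 14.33, with array medians from 8.25 to 8.32. RMA assumes that most genes keep their level and pulls dim probe sets towards a common floor, so that a fold change of a dim gene is understated and a shift shared by most genes would not be seen. No detection call comes with the values, so which probe sets lie above background is unknown, and the number of arrays limits the precision.

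The table held 35556 probe sets. Of these 21789 were paired with 1 gene symbol in the array platform's annotation as held by GEO, 1621 with several and 12146 with none. Probe sets with several symbols or none were unnamed here and left out of the main test. Entrez identifiers of 21698 of the 21789 matched a table of mouse genes on the assembly GRCm38.p6, and 0 symbols needed updating. This table served only for names and for the order of neighbouring genes, and no coordinates are given, since the build of the files is not known. A gene with more than 1 probe set, as for 999 genes, was represented by the probe set with the highest mean over the 8 arrays, which left 19938 genes.

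Differences between the genotypes were fitted on the log2 values with lmFit and eBayes in limma 3.58.1 under R 4.3.3, with 1 coefficient for genotype and no covariate. All adjusted p of genes are limma's, adjusted by Benjamini-Hochberg over the genes tested, and a gene was called changed at an adjusted p under 0.05. Errors printed as SE are those of the moderated fit, and values printed as mean ± SD are over 4 uteri. A second count required a change of at least 1.5-fold. Changes are given as deleted minus control.

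The 29 gene lists were written from textbook knowledge before the data were examined. They cover cell types of the uterus and of tissue that can be dissected with it, hormone responses, signalling pathways and secretory functions. Of each list were counted the members past the threshold over all genes tested, and past it when p was adjusted over the list alone. Each list was compared with all other genes by camera in limma with a preset correlation between genes of 0.01, adjusted over the lists, and again with a correlation estimated per list. The fry test was run beside it. Lists share members, so their results are not independent. Genes near the engineered loci were compared with all other placed genes by a two-sided Fisher exact test, over up to 100 tested genes on each side of Foxa2 and of Pgr on the same chromosome, which held 33 on one side of Pgr.

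The genes named were set by a rule fixed before the data were examined. They are Foxa2 and Pgr, the 15 genes with the largest increase and the 15 with the largest decrease among those past the threshold whose 4 values in one group all lay above the 4 of the other, and in each list up to 4 members past the threshold with the smallest adjusted p, or the 2 with the smallest p where none passed. Genes with a predicted symbol counted in the rule and were not described. Names outside this rule are marked where they appear.

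Comparisons of single values between 4 and 4 arrays used two-sided exact permutation tests over all 70 arrangements, for which the smallest possible p is 0.029. The steps were tested on simulated data made from the spread of these arrays, with 19938 genes. Of 100 genes changed 1.5-fold 88% were called, of 50 changed 2-fold 98%, and of 50 changed 4-fold 100%, with 7 unchanged genes called (3.61% of all calls). With no list changed 0 of the 29 lists passed, and 1 list raised by 0.5 was found, also with an estimated correlation. Each simulated gene was drawn independently of the others and with the same spread in both groups. Correlations estimated from the real arrays reached 0.76 for smooth muscle markers and 0.72 for pan-epithelial genes. The simulation therefore does not give the error rate or power for lists of correlated genes.

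Alternatives covered 3 other scalings (quantile normalisation applied again, centring on the array median, cyclic loess), leaving out the dimmest 25% or the lower 50% of genes, an intensity trend and robust shrinkage in eBayes, array weights, the replicate number as a block, every probe set counted, the mean of a gene's probe sets, other set tests, windows of 50 and 200 genes around the loci, and each array left out in turn. A fit with the adipose list mean as a covariate was added after the data were seen.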

Results

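Gene expression was measured in the whole uterus of 8 female mice, 4 controls and 4 in which Foxa2 had been deleted, with 1 microarray per uterus. FOXA2 is a forkhead transcription factor of the endometrial glands, the epithelial glands that secrete into the uterine lumen. The deleted animals carried floxed Foxa2 alleles and a Cre recombinase inserted at 1 of their alleles of the progesterone receptor gene Pgr, so that Cre was made in cells that use Pgr. The controls had intact Foxa2, 2 intact Pgr alleles and no Cre. All females had been mated to vasectomised males and were sampled on day 3.5 of pseudopregnancy, counted from the day of the vaginal plug as day 0.5. Such mating is used to bring on the hormones of early pregnancy with no embryos present. Hormone levels were not part of these data, so whether they were alike in both genotypes is unknown. The comparison asks which transcripts differ between whole uteri with and without the Foxa2 deletion. Whole tissue does not separate a change of transcript per cell from a change in the number of cells, such as those of glands. When Foxa2 was lost, and whether glands had formed, was not measured here. Since Cre and the Pgr genotype differed together with Foxa2, each difference below is one between these 2 genotypes. The median log2 intensity lay between 8.25 and 8.32 on the 8 arrays, and the number of arrays limits the precision.

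The probe set for Foxa2 fell by 0.52 on the log2 scale (SE 0.05, adjusted p = 0.0013, limma), from 8.72 ± 0.09 (SD, n = 4) in controls to 8.21 ± 0.01 (SD, n = 4) in deleted uteri. Every deleted uterus lay between 8.20 and 8.22 and every control between 8.61 and 8.82, so the 8 arrays followed their labels. Whether this probe set (identifier 10488374) lies inside the deleted part of the gene is not given in the sources used here. Pgr, the receptor that mediates the uterine response to progesterone, rose by 0.37 (SE 0.10, adjusted p = 0.043, limma), from 11.23 ± 0.05 to 11.60 ± 0.21 (SD, n = 4 each). This call was lost on omitting any 1 of the 4 controls, Foxa2-deleted replicate 1 or Foxa2-deleted replicate 4, with adjusted p up to 0.105, and under repeated quantile normalisation (adjusted p = 0.0505).

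Spink1, which encodes a Kazal-type trypsin inhibitor, was 19.5-fold lower (log2 change -4.28, SE 0.26, adjusted p = 2.4e-04) and went from 9.80 ± 0.62 to 5.52 ± 0.09 (SD, n = 4 each). Cxcl15, which encodes a chemokine of the endometrial glands, was 15.8-fold lower (log2 change -3.98, SE 0.11, adjusted p = 4.5e-07). In the other direction Clca1, which encodes a secreted regulator of chloride channels, was 23.3-fold higher (log2 change 4.54, SE 0.32, adjusted p = 3.5e-04). The iron-sequestering proteins lipocalin 2 (Lcn2) and lactotransferrin (Ltf) were 19.0-fold and 18.1-fold higher, with log2 changes of 4.25 (SE 0.12) and 4.17 (SE 0.25) and adjusted p of 4.5e-07 and 2.4e-04.

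Among the 15 genes with the largest increases, the membrane mucin Muc4 rose by 3.71 (SE 0.28), and 3 genes of the small proline-rich family of the cornified envelope, Sprr2d, Sprr2f and Sprr2b, rose by 3.44 (SE 0.44), 3.42 (SE 0.28) and 3.15 (SE 0.39). The protease inhibitor gene A2m rose by 3.15 (SE 0.22), the arginase gene Arg1 by 3.13 (SE 0.41) and Gabrp, a GABA receptor subunit gene, by 3.13 (SE 0.51). Apobec2, the alkaline phosphatase gene Alpl, the connexin 26 gene Gjb2 and the serine protease gene Tmprss11d rose by 3.12 (SE 0.46), 3.07 (SE 0.32), 2.83 (SE 0.39) and 2.77 (SE 0.43). Their adjusted p ranged from 3.5e-04 for A2m to 0.0112 for Gabrp. Chil1, a chitinase-like gene, had a log2 change of 3.44 with a larger error (SE 0.82, adjusted p = 0.034), since its deleted uteri ran from 7.84 on replicate 1 to 12.60 on replicate 3. Its call was lost without any 1 of the controls or without Foxa2-deleted replicate 4, with adjusted p up to 0.0923.

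Among the 15 genes with the largest decreases, the cytosolic sulfotransferase gene Sult1d1 fell by 3.53 (SE 0.68, adjusted p = 0.017), and Cyp3a57 by 2.90 (SE 0.18). Sbspon fell by 2.24 (SE 0.36), Nxpe2 by 2.08 (SE 0.16) and Cyp1b1, a cytochrome P450 that hydroxylates estrogens, by 1.97 (SE 0.23). The organic anion transporter gene Slco4c1, the monoamine oxidase gene Maob, the granzyme gene Gzmb and the keratin gene Krt23 were lower, with log2 changes of -1.92 (SE 0.21), -1.92 (SE 0.36), -1.84 (SE 0.32) and -1.80 (SE 0.25). Lrp2, the endocytic receptor megalin, fell by 2.73 (SE 0.68, adjusted p = 0.038), Slc2a3, the glucose transporter GLUT3, by 1.85 (SE 0.47, adjusted p = 0.040) and Apela, a ligand of the apelin receptor, by 1.87 (SE 0.41, adjusted p = 0.026). In these 3 genes Foxa2-deleted replicate 2 stayed nearest the controls, as with Lrp2 at 11.03 against 8.60 or less on the other deleted arrays and 11.43 ± 0.19 (SD, n = 4) in controls. That array was also the nearest in Sult1d1, Cyp3a57, Sbspon, Cyp1b1, Slco4c1, Maob, Gzmb and Krt23. In Spink1, Cxcl15 and Nxpe2 another deleted array was nearest. The calls of Lrp2 and Slc2a3 were lost without any 1 array other than Foxa2-deleted replicate 2, with adjusted p up to 0.103 and 0.108. That of Apela was lost without any 1 control or Foxa2-deleted replicate 1 (adjusted p up to 0.0802), that of Sult1d1 without control replicate 2, 3 or 4 (up to 0.0593) and that of Maob without control replicate 2 or 4 (up to 0.0551).

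**Figure D1:**
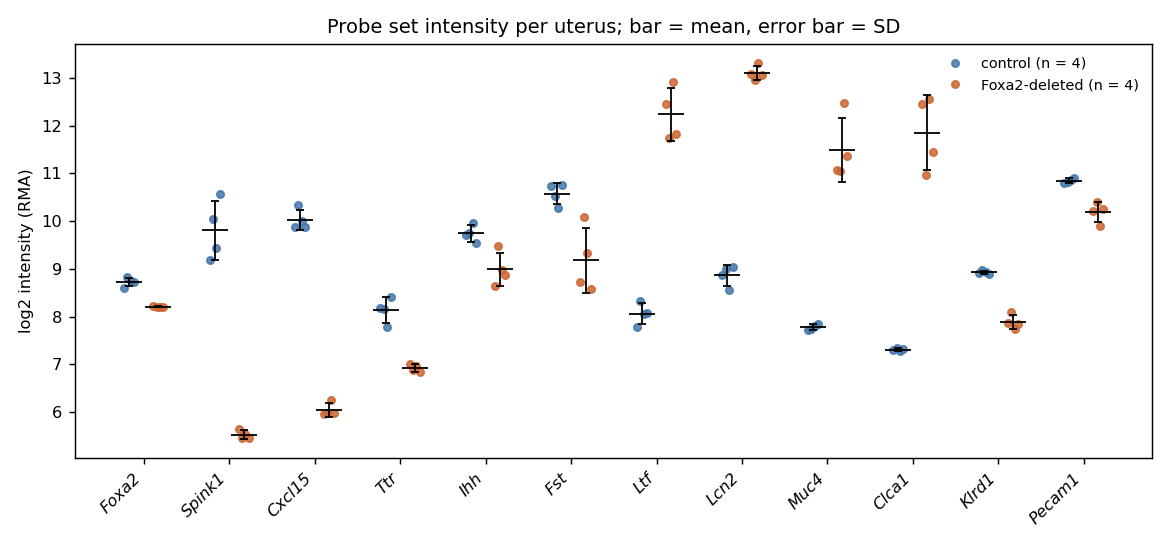
The plot shows the log2 intensity (RMA) of 12 genes in each of the 8 uteri, with points for uteri, long bars for group means and error bars for SD (n = 4 per group). Spink1 and Cxcl15 lay at 6.25 or below in all deleted uteri, while Lcn2 lay at 12.96 or above in them and at 9.04 or below in controls.

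Over all 19938 genes tested, 2209 (11.1%) changed at an adjusted p under 0.05 (limma, Benjamini-Hochberg), of which 898 were higher and 1311 lower in deleted uteri. Under centring of each array on its median the split was 1082 higher and 982 lower. Of the 2209 genes, 653 changed at least 1.5-fold, with 351 higher and 302 lower, and at least 4-fold changes were found for 45 genes higher and 8 lower. The 4 values of one group all lay above the 4 of the other in 4215 genes (21.1%), where chance gives 2.86%, and in 2155 of the 2209. Deleted uteri varied more than controls. The correlation between arrays across genes, which are not independent replicates, ranged from 0.9805 to 0.9900 among deleted uteri and from 0.9961 to 0.9968 among controls. Each deleted array was placed on a scale where the control mean is 0 and the mean of the other deleted arrays is 1. Foxa2-deleted replicates 1 to 4 lay at 0.946, 0.561, 1.38 and 0.756. The count of changed genes was 1111, 557, 618 and 556 without control replicates 1, 2, 3 and 4. It was 1069, 2947, 1868 and 3059 without Foxa2-deleted replicates 1, 2, 3 and 4. The count of genes changed at least 1.5-fold was 395, 274, 284 and 270 without the controls in the same order, and 436, 966, 534 and 728 without the deleted replicates. Of the 99 genes named here besides Foxa2 and Pgr, 58 stayed on their side of the threshold with each array left out in turn.

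Gene lists fixed before the data were examined were compared with all other genes (camera in limma), and 15 of the 29 lists passed an adjusted p of 0.05, 10 with higher and 5 with lower genes. None passed with a correlation between genes estimated from these arrays, and other divisions of the 8 arrays into 4 and 4 also gave 15 lists. With fry, which asks whether a list's genes move one way without comparing them with other genes, 13 lists passed, and 25 passed its test for change in either direction.

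Of 16 endometrial gland markers measured, 6 fell, 1 rose and 9 did not pass, and adjusted over the list alone 6 fell and 3 rose. Besides Foxa2, Spink1 and Cxcl15, the transthyretin gene Ttr fell by 1.22 (SE 0.12, adjusted p = 0.0013). The list as a whole was lower (median -0.21, adjusted p = 0.025, and adjusted p = 0.321 with an estimated correlation). That call was lost without Foxa2-deleted replicate 2 (adjusted p = 0.0755) or replicate 4 (adjusted p = 0.0693) and on ranks (adjusted p = 0.236), and the direction turned with the dimmer genes left out. Of the marker lists for the rest of the epithelium, 9 of 28 pan-epithelial genes rose and none fell (17 and 0 adjusted over the list alone; median 0.45). Krt19, Krt7, the epithelial transcription factor gene Elf3 and the mucin Muc1 rose by 1.86 (SE 0.22), 1.52 (SE 0.27), 1.77 (SE 0.25) and 1.57 (SE 0.25), with adjusted p from 0.0034 to 0.0139. The pan-epithelial list was higher at adjusted p = 1.3e-06, and at adjusted p = 0.467 with an estimated correlation. Of 14 luminal epithelium markers, 5 rose and 2 fell (5 and 3 adjusted over the list alone; median 0.23, adjusted p = 0.309, and 0.476 with an estimated correlation). Sprr2f, Gabrp and the retinoic acid binding protein gene Crabp2 (log2 change 1.05, SE 0.25) were among the higher. The hedgehog ligand gene Ihh, a luminal target of progesterone, fell by 0.76 (SE 0.16, adjusted p = 0.025). The call of Crabp2 was lost without any 1 of 6 arrays, namely the controls and Foxa2-deleted replicates 1 and 3, with adjusted p up to 0.0936, and that of Ihh without any 1 control or Foxa2-deleted replicate 1, with adjusted p up to 0.0776.

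Of 23 genes known to respond to estrogen in the uterus, 15 rose, none fell and 8 did not pass (16 higher and 1 lower adjusted over the list alone). Clca1, Ltf, Lcn2 and Muc4, described above, led the list, whose median was 1.16 (adjusted p = 4.3e-11, and adjusted p = 0.321 with an estimated correlation). Of 18 genes known to respond to progesterone, 8 fell, none rose and 10 did not pass (12 lower and 0 higher adjusted over the list alone). The activin antagonist gene Fst fell by 1.40 (SE 0.30), the zinc finger gene Zbtb16 by 1.46 (SE 0.33) and the chaperone gene Fkbp5 by 0.71 (SE 0.16), with adjusted p from 0.024 to 0.028, and Ihh is a member too. The progesterone-responsive list had a median of -0.73 (adjusted p = 5.5e-06, and adjusted p = 0.326 with an estimated correlation). Relative to the control mean, its mean lay at -1.14, -0.15, -1.10 and -0.93 on Foxa2-deleted replicates 1 to 4, while the estrogen-responsive mean lay at 1.40, 1.17, 1.82 and 1.26. The calls of Zbtb16 and Fkbp5 were lost without any 1 control (adjusted p up to 0.0825 and 0.0816), and that of Fst without any 1 control or Foxa2-deleted replicate 1 (up to 0.0761).

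Of 25 cell cycle genes, 10 rose, none fell and 15 did not pass (15 higher and 0 lower adjusted over the list alone). The mitotic kinase gene Plk1 rose by 0.70 (SE 0.06, adjusted p = 7.2e-04), Ccna2, which encodes cyclin A2, by 0.55 (SE 0.05, adjusted p = 9.4e-04) and Cdc20, an activator of the anaphase-promoting complex, by 0.50 (SE 0.04, adjusted p = 7.9e-04). The spindle assembly gene Tpx2, one of the neighbours of Foxa2 in gene order, rose by 0.41 (SE 0.05, adjusted p = 0.0036). The list median was 0.21 (adjusted p = 6.0e-07, and adjusted p = 0.321 with an estimated correlation).

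**Figure D2:**
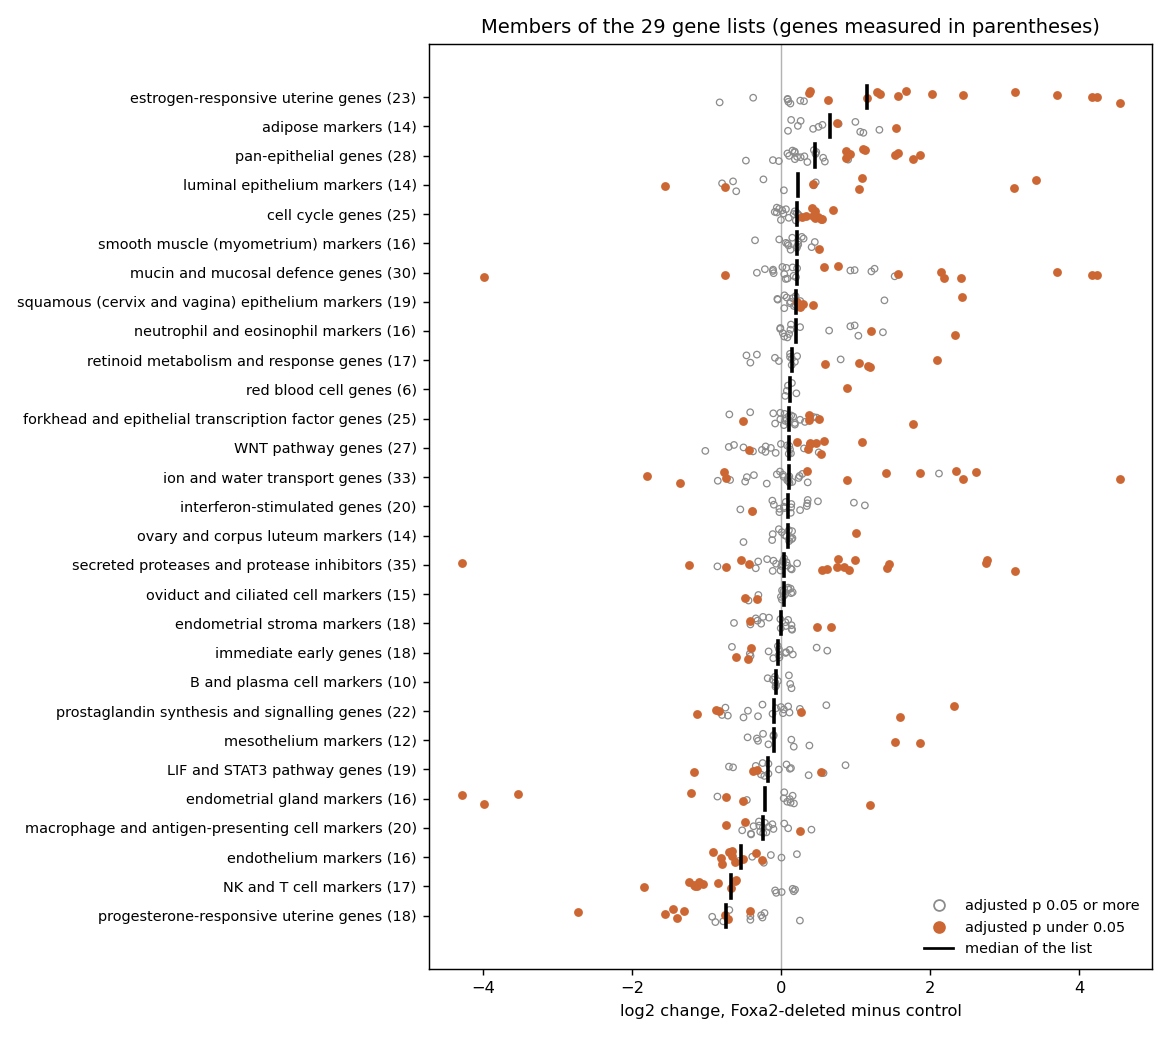
The plot shows the log2 change, deleted minus control, of every measured member of the 29 gene lists, with filled points for members past an adjusted p of 0.05 and a bar for each list's median. The medians ran from -0.73 for progesterone-responsive genes to 1.16 for estrogen-responsive genes.

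Of 30 mucin and mucosal defence genes, 9 rose, 2 fell and 19 did not pass (15 higher and 4 lower adjusted over the list alone; median 0.21, adjusted p = 1.3e-04, and adjusted p = 0.321 with an estimated correlation). Lcn2, Ltf and Muc4 were among the higher and Cxcl15 among the lower. Relative to the control mean, the mean of this list lay at 0.68, 0.59, 1.19 and 0.62 on Foxa2-deleted replicates 1 to 4. Of 35 secreted proteases and protease inhibitors, 12 rose and 5 fell, and the same numbers passed adjusted over the list alone (median 0.04, adjusted p = 0.134, and 0.514 with an estimated correlation). A2m and Tmprss11d were among the higher, and Spink1 and Serpinb9, an inhibitor of granzyme B, which fell by 0.43 (SE 0.07, adjusted p = 0.0105), among the lower. This list passed without Foxa2-deleted replicate 2 (adjusted p = 0.0394) or replicate 3 (adjusted p = 0.0292). Of 33 ion and water transport genes, 8 rose and 4 fell (10 and 6 adjusted over the list alone; median 0.10, adjusted p = 0.101, and 0.479 with an estimated correlation). The phosphate transporter gene Slc34a2 and the chloride channel gene Cftr rose by 2.62 (SE 0.38) and 2.44 (SE 0.31), and the bicarbonate transporter gene Slc4a4 fell by 0.77 (SE 0.11), with adjusted p of 0.0074, 0.0040 and 0.0076. The transport list passed without Foxa2-deleted replicate 3 (adjusted p = 0.0458) and with the dimmest 25% of genes left out (adjusted p = 0.0494).

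Of 17 retinoid genes, 5 rose and none fell, and the same numbers passed adjusted over the list alone (median 0.14, adjusted p = 0.021, and adjusted p = 0.321 with an estimated correlation; adjusted p = 0.095 without Foxa2-deleted replicate 4). The retinol dehydrogenase gene Dhrs9 rose by 2.10 (SE 0.35) and the retinoic acid synthesis genes Aldh1a2 and Aldh1a1 by 1.17 (SE 0.21) and 1.20 (SE 0.27), with adjusted p of 0.012, 0.015 and 0.027. Aldh1a1, also the 1 gland marker that rose, lost its call without any 1 control or Foxa2-deleted replicate 1 (adjusted p up to 0.0793). Crabp1 rose by 0.59 (SE 0.12, adjusted p = 0.021), a call lost without control replicate 2 or 3 (adjusted p up to 0.0647). Of 25 forkhead and epithelial transcription factor genes, 4 rose and 1, Foxa2, fell (5 and 1 adjusted over the list alone). Besides Elf3 and Pgr these were the forkhead gene Foxl2, by 0.37 (SE 0.05, adjusted p = 0.0059), and the grainyhead gene Grhl3, by 0.51 (SE 0.09, adjusted p = 0.0123). The list median was 0.10 (adjusted p = 0.033, and adjusted p = 0.321 with an estimated correlation). This list did not pass under 3 other scalings (adjusted p from 0.0519 to 0.0745) nor without control replicate 1 or 2 or Foxa2-deleted replicate 4 (up to 0.0766). Of 19 LIF and STAT3 pathway genes, 3 fell and 1 rose (5 and 2 adjusted over the list alone; median -0.17, adjusted p = 0.134, and 0.514 with an estimated correlation; adjusted p = 0.0096 without Foxa2-deleted replicate 3). Il6st, the shared receptor subunit gp130, fell by 0.38 (SE 0.05, adjusted p = 0.0049). Jak1 fell by 0.33 (SE 0.08) and Igfbp3 by 1.17 (SE 0.28), while the interleukin 4 receptor gene Il4ra rose by 0.54 (SE 0.14), with adjusted p of 0.041, 0.035 and 0.046. Each of these 3 calls was lost without most single arrays, with adjusted p up to 0.118, 0.102 and 0.124, and held without Foxa2-deleted replicate 2 for Jak1 and Il4ra and without replicate 4 for Igfbp3 and Il4ra.

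Markers of other cell types moved apart. Of 16 endothelium markers, 10 fell, none rose and 6 did not pass (12 lower and 1 higher adjusted over the list alone). The endothelial adhesion genes Pecam1 and Esam fell by 0.66 (SE 0.10) and 0.81 (SE 0.15), the receptor gene Tie1 by 0.70 (SE 0.11) and Egfl7 by 0.62 (SE 0.11), with adjusted p from 0.0077 to 0.0166. The endothelial list had a median of -0.54 (adjusted p = 2.6e-06, and adjusted p = 0.321 with an estimated correlation). The call of Esam was lost without control replicate 2, 3 or 4 (adjusted p up to 0.0572). Of 17 NK and T cell markers, 11 fell, none rose and 6 did not pass, with the same numbers adjusted over the list alone. The 6 were Ccl5 at -0.06 and the T cell genes Cd3d, Cd3e, Cd3g, Cd4 and Cd8a, at -0.08 to 0.19, which are named after their values were seen. Control means of these T cell genes ran from 6.80 to 8.63, and a fall of the dimmest may not show. The NK receptor genes Klrd1, Klrb1c and Klrk1 fell by 1.04 (SE 0.07), 1.17 (SE 0.09) and 0.85 (SE 0.11), and Txk, a kinase of T and NK cells, fell by 0.60 (SE 0.07), with adjusted p from 3.5e-04 to 0.0038. The NK and T cell list had a median of -0.67 (adjusted p = 9.1e-06, and adjusted p = 0.321 with an estimated correlation; adjusted p = 0.163 with the lower 50% of genes by mean intensity left out). Of 16 neutrophil and eosinophil markers, 2 rose and none fell (6 and 0 adjusted over the list alone; median 0.19, adjusted p = 0.0012, and adjusted p = 0.467 with an estimated correlation). The neutrophil genes Cxcr2 and Ly6g rose by 2.33 (SE 0.43) and 1.21 (SE 0.25), with adjusted p of 0.015 and 0.021. The mean of this list lay 1.14 above the control mean on Foxa2-deleted replicate 3 and 0.43, 0.41 and 0.33 above it on replicates 1, 2 and 4, and Cxcr2 stood at 9.61 on replicate 3 and at 7.79 or less on the other deleted arrays. The call of Cxcr2 was lost without control replicate 2 or 3 (adjusted p up to 0.0539), and that of Ly6g without any 1 control or Foxa2-deleted replicate 1 (up to 0.066).

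Of 20 macrophage and antigen-presenting cell markers, 2 fell and 1 rose (3 and 1 adjusted over the list alone). The integrin gene Itgax fell by 0.74 (SE 0.07, adjusted p = 7.9e-04) and the leukocyte gene Ptprc by 0.49 (SE 0.10, adjusted p = 0.024), while the scavenger receptor gene Cd163 rose by 0.25 (SE 0.07, adjusted p = 0.049). The list had a median of -0.24 (adjusted p = 0.028, and adjusted p = 0.542 with an estimated correlation), and it did not pass without control replicate 2 or 4 or Foxa2-deleted replicate 2 or 4, with adjusted p up to 0.174. Nor did it pass with array weights (adjusted p = 0.0513), with fry (adjusted p = 0.194), with the lower 50% of genes left out (adjusted p = 0.335) or with the mean of adipose markers as a covariate (adjusted p = 0.587). The call of Ptprc was lost without any 1 control (up to 0.078), and that of Cd163 without any 1 array other than control replicate 1 (up to 0.132). None of 10 B and plasma cell markers passed at an adjusted or list-alone level (median -0.07, adjusted p = 0.745, and 0.877 with an estimated correlation); Blk, at 0.14 (SE 0.08), had an adjusted p of 0.247. Of 18 endometrial stroma markers, the collagen genes Col6a1 and Col6a3 rose by 0.49 (SE 0.08) and 0.67 (SE 0.15) and the nuclear receptor gene Nr2f2 fell by 0.41 (SE 0.10), with 15 not passing (2 higher and 4 lower adjusted over the list alone). The stromal median was -0.0075 (adjusted p = 0.745, and 0.877 with an estimated correlation). The calls of Col6a3 and Nr2f2 were lost without any 1 control, with adjusted p up to 0.0753 and 0.0995, and that of Nr2f2 also without Foxa2-deleted replicate 1. Of 16 smooth muscle markers, the actin gene Actg2 alone passed, at 0.51 (SE 0.13, adjusted p = 0.045), and 0 passed adjusted over the list alone. The muscle median was 0.21 (adjusted p = 0.0098, and adjusted p = 0.541 with an estimated correlation), a call lost without Foxa2-deleted replicate 1 (adjusted p = 0.0769). The call of Actg2 held only without Foxa2-deleted replicate 4 among single omissions (adjusted p up to 0.12).

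Tissue next to the uterus was looked for in the same way. Of 14 adipose markers, 2 rose and none fell, with the same numbers adjusted over the list alone. The fatty acid binding protein gene Fabp4 had a log2 change of 1.55 (SE 0.42, adjusted p = 0.0496) and the lipid droplet gene Plin4 of 0.75 (SE 0.17, adjusted p = 0.026). Fabp4 lost its call without any 1 of 6 arrays (adjusted p up to 0.132) and Plin4 without control replicate 2, 3 or 4 (up to 0.0802). The adipose median was 0.65 (adjusted p = 4.5e-04, and adjusted p = 0.467 with an estimated correlation). Its mean on single arrays overlapped between the groups, from -0.45 to 0.59 in controls and from 0.16 to 1.02 in deleted uteri (difference 0.70, two-sided exact permutation p = 0.0857, n = 4 each). With this mean as a covariate, chosen after the data were seen, 160 genes changed instead of 2209 and 125 instead of 653 at least 1.5-fold. All 2209 kept their direction under it, with a median ratio of 1.04 for the log2 change and of 1.40 for the SE. The same covariate shuffled within groups gave a median of 151.5 calls over 50 draws (77 to 1928). Of 19 squamous markers of cervix and vagina, 5 rose and none fell (6 and 0 adjusted over the list alone; median 0.20, adjusted p = 1.3e-04, and adjusted p = 0.321 with an estimated correlation). The cornified envelope gene Sprr1a rose by 2.43 (SE 0.32, adjusted p = 0.0047), while Krt4 and Ivl, at 0.21 (SE 0.05) and 0.25 (SE 0.06), changed little, with adjusted p of 0.024 and 0.037 that rose as high as 0.0781 and 0.108 without 1 array. Krt13 rose by 0.43 (SE 0.11, adjusted p = 0.043), a call lost without any 1 of 6 arrays (adjusted p up to 0.118). Of 15 oviduct and ciliated cell markers, the axonemal genes Dnah5 and Cfap126 fell by 0.48 (SE 0.07, adjusted p = 0.0056) and 0.33 (SE 0.07, adjusted p = 0.025) and none rose (0 higher and 3 lower adjusted over the list alone). The median of that list was 0.03 and its mean -0.05 (adjusted p = 0.805, and 0.877 with an estimated correlation). The call of Cfap126 was lost without any 1 control or Foxa2-deleted replicate 1 (adjusted p up to 0.08). Of 12 mesothelium markers only Krt19 and Krt7, which are epithelial keratins, rose, also adjusted over the list alone. Its median was -0.10 and its mean 0.20 (adjusted p = 0.745, and 0.877 with an estimated correlation). Of 14 ovary and corpus luteum markers, Inhba, which encodes an activin subunit, rose from 7.89 ± 0.15 to 8.90 ± 0.49 (SD, n = 4 each, adjusted p = 0.024, limma) and 13 did not pass, with 1 passing adjusted over the list alone (median 0.09, adjusted p = 0.203, and 0.479 with an estimated correlation). Inhba lost its call without any 1 control or Foxa2-deleted replicate 1 (adjusted p up to 0.0766).

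**Figure D3:**
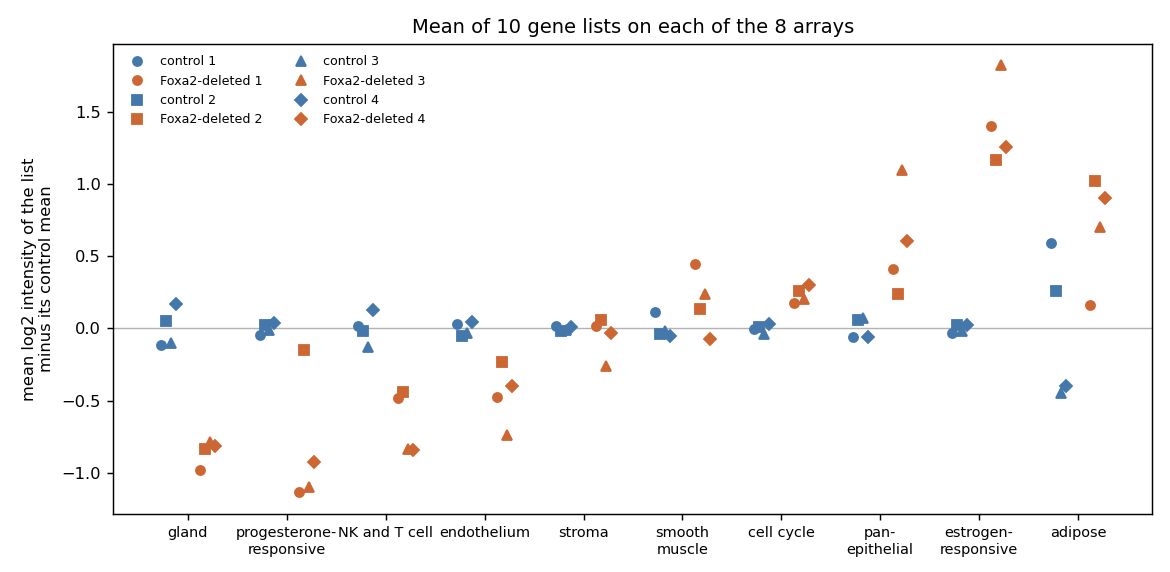
The plot shows the mean log2 intensity of 10 gene lists on each of the 8 arrays, minus the mean of the controls, with colour for genotype and shape for replicate number. Estrogen-responsive means lay at 1.17 or above on all deleted arrays, while the progesterone-responsive mean lay at -0.15 on Foxa2-deleted replicate 2 and at -0.93 or below on the others.

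Genes near the engineered loci were counted because strain sequence can travel with a floxed or Cre allele. Among up to 100 tested genes on each side of Foxa2 and of Pgr, where the chromosome ended after 33 on one side of Pgr, 28 of 333 changed (8.41%), against 2177 of 19521 elsewhere (11.2%). The odds ratio was 0.731 (95% interval 0.477 to 1.08, two-sided Fisher exact p = 0.134), with 17 of 200 near Foxa2 and 11 of 133 near Pgr. With windows of 50 and 200 genes the odds ratio was 0.765 (Fisher exact p = 0.346) and 0.995 (p = 1). It was 0.630 (Fisher exact p = 0.0387) with cyclic loess scaling and 0.645 (p = 0.0392) with robust variance shrinkage, and no other alternative had a p under 0.05.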

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

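The tests of other divisions of the arrays were chosen before the result was seen, and all other tests weighed here after it. Single samples that stood apart from the other 3 of their group were looked for among the 101 named genes by the gap of the highest or lowest value to its neighbour as a share of the group's range. Chance alone passes the tabulated 5% critical value in about 10.1 of the 202 groups tested, and 15 passed. On Foxa2-deleted replicate 3, Alpl was high at 12.36 (gap 0.894 of the range), Tmprss11d at 10.15 (0.854) and Cxcl15 at 6.25 against 5.97 or less on the others (0.966). On Foxa2-deleted replicate 2, Gjb2 was low at 8.91 against 10.67 or more (0.907) and Pla2g10 high at 9.60 against 8.77 or less (0.883). Plin4 was low on Foxa2-deleted replicate 1 at 9.27 (0.83) and Tpx2 high on replicate 4 at 9.45 (0.833). Among controls, Sprr2f was low on replicate 4 at 7.55 (0.837), Cyp1b1 high on replicate 4 at 9.63 (0.883) and Dnah5 low on replicate 4 at 7.62 (0.90). On control replicate 3, Gm32592 was low at 9.41 (0.90), Pou2af1 low at 7.71 (0.889), Ptger2 high at 8.37 (0.857) and Cfap126 low at 7.59 (0.857). Col6a1 was at 11.78 on control replicate 1 and at 11.75 on each of the other controls, a gap equal to the whole range (1) that comes from values rounded to 2 decimals.

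Probe sets without a gene symbol were not used in the report. Of these 12146, 733 passed an adjusted p of 0.05 when all 35556 probe sets were tested with limma, 185 of them higher and 548 lower in deleted uteri.

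Of the 35 ways to divide the 8 arrays into 4 and 4, only the real one (1 of 35) gave as many changed genes. It gave 2209, against 0 at most in the others. The same held for genes changed at least 1.5-fold, with 653 against 0 at most and 1 of 35 divisions as large. A share of 1 in 35 is the smallest possible here, so chance is made unlikely and not excluded. Every other division mixes the genotypes, and their difference then adds to the spread within groups, which lowers its count. Nor can divisions tell genotype from another factor that follows the groups. For the number of lists chance is not made unlikely, since 3 of the 35 divisions gave as many, the real one with 15 and the highest other with 15. Both of the others exchanged 1 array between the genotypes, control replicate 4 for Foxa2-deleted replicate 2 or control replicate 3 for Foxa2-deleted replicate 1.

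In deleted uteri 15 of 23 estrogen-responsive genes were called higher and 8 of 18 progesterone-responsive genes lower, and neither list passed with an estimated correlation (adjusted p = 0.321 and 0.326). For a larger epithelial share of the RNA, list means were compared without the genes they share (Muc1, and Nr2f2 with Hand2 and Hoxa10, which are outside the naming rule). The change of the estrogen-responsive mean exceeded that of the pan-epithelial mean by 0.85 (two-sided exact permutation p = 0.0286, the smallest possible). The change of the progesterone-responsive mean lay below that of the stromal mean (difference of the changes -0.93, exact permutation p = 0.0286, n = 4 each). Each list thus moved further than the one beside it. This does not settle the epithelial share, since the lists were compared after their changes were seen. Pan-epithelial genes also do not tell glands from lumen, and the progesterone-responsive list holds luminal genes such as Ihh. Adipose tissue in some samples was weighed too, through a list that had 14 measured genes and shares 0 with any other list (Fabp4 at 9.43 in controls and 10.98 in deleted uteri). With its mean as a covariate the log2 change of the 23 called members kept a median ratio of 1.11 (0.919 to 1.32). This argues against adipose tissue for these 23 genes. They were picked as called without the covariate on the same arrays, and over all called genes the median ratio was 1.04. With 8 arrays the test has little power. The drop from 2209 to 160 calls under that covariate came with a median SE 1.40 times as large, and the same covariate shuffled within groups gave a median of 151.5 calls over 50 draws (77 to 1928). The effect of 1 Pgr allele carrying Cre cannot be told apart from that of Foxa2. No Cre carrier with intact Foxa2 is in the design. The change of Pgr itself does not decide, as its probe set may read both alleles. It was 0.37, a call lost in 6 of 8 fits with 1 array left out. Hormone levels of the animals were not part of these data. The loss of Foxa2 thus stays one candidate explanation among those open.

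Foxa2-deleted replicate 2 showed the smallest change over all genes, at 0.561 where the control mean is 0 and the mean of the other deleted arrays is 1. Glands left in that uterus could keep gland transcripts up. Over the 6 gland markers that fell, the drop there had a median of 1.02 times that on the other deleted arrays. Of the 6, 5 lay above 0.8. The exception was Sult1d1, at 0.514, which kept 23.9% of the control level there and 22.2% on Foxa2-deleted replicate 4. These 6 were picked as called lower on the same arrays, which favours genes that fell on every deleted array, and they include Foxa2 itself. Relative to the control mean, the mean of all measured gland markers lay at -0.83 on Foxa2-deleted replicate 2. It lay from -0.98 to -0.78 on the other deleted arrays, and it includes the same 6 genes. These values therefore cannot tell whether glands were left in that uterus. A compressed scale on that array that acted alike at all intensities would shrink all sets by the same share. The median share of the change kept was 0.733 over 15 estrogen-responsive genes (quartiles 0.498 and 0.848) and 0.297 over 8 progesterone-responsive genes (0.218 and 0.323), a difference of 0.436. This argues only against such an even compression. The 2 sets were picked as called on these arrays and were not matched for intensity, so a compression that depends on intensity stays open. No other biological explanation was tested, and one in which the hormone response of that animal differed, with its progesterone-responsive mean at -0.15, may hold.

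In deleted uteri 10 of 16 endothelium markers and 11 of 17 NK and T cell markers were called lower, and neither list passed with an estimated correlation (adjusted p = 0.321 for each). Dilution by a larger share of other RNA could lower them. The mean of the 2 lists fell further than that of stroma and smooth muscle (difference -0.62, two-sided exact permutation p = 0.0286, the smallest possible, n = 4 each). Smooth muscle itself rose by 0.19 and may be part of the other RNA, so this comparison cannot exclude dilution. Stroma moved by -0.06, against -0.46 for endothelium and -0.65 for NK and T cell markers. A dilution that reached stroma to the same degree was thus not seen. Fewer such cells and less transcript per cell stay open, as does the Pgr genotype, and none of these was tested. The fall was not seen in the 5 T cell markers of the list, which lay between -0.08 and 0.19 with no call. Their control means ran from 6.80 for Cd3d to 8.63 for Cd3e. Background is unknown, so a fall of the dimmest of them may not show, and T cells cannot be said to be spared.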

How the results depend on the processing

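The adipose covariate was chosen after the data were seen, and all other alternatives before. Foxa2 kept its direction and its call in every setting that tested it, from -0.55 to -0.48 with 1 array left out. Foxa2 and the count near the loci had no value with the lower 50% of genes by mean intensity left out, which removed Foxa2. Over 99 other named genes and all settings, 1739 values held 0 reversals and 301 lost calls. Counts of changed genes moved by more than 1.5 times as follows, and the cause was not tested unless stated. With 1 array left out, changed genes numbered 556 to 3059 (196 to 1374 higher, 348 to 1777 lower), those changed at least 1.5-fold 270 to 966 (110 to 490 higher, 151 to 476 lower), named genes past the threshold 59 to 95 of 101 (99 with all arrays), lists 11 to 19, and the odds ratio near the loci ran from 0.628 to 0.920. The count rose to 2947 and 3059 without Foxa2-deleted replicates 2 and 4, so a smaller number of samples alone does not account for this range. Pgr ranged from 0.30 to 0.45 with 1 array left out, and was 0.36 after repeated quantile normalisation (adjusted p = 0.0505). With the lower 50% left out, 9973 genes were tested, 533 rose, 187 fell at least 1.5-fold and 65 named genes passed. Pgr and the 64 other named genes still tested all kept their calls, so this lower count comes from named genes that were removed. The gland list then turned to higher with no call (adjusted p = 0.991, and from 0.00267 to 0.0755 with 1 array left out), since Foxa2, Spink1, Cxcl15 and Ttr were among the genes removed. Array weights gave 3132 changed genes, 1351 of them higher. The replicate block gave 1062 changed genes (435 higher, 627 lower), 461 of them at least 1.5-fold (230 higher), left Pgr at 0.37 without a call (adjusted p = 0.0777) and changed no list's call. The replicate numbers did not pair the arrays, with correlations of deviations between same-numbered arrays of 0.0568, -0.0506, -0.0261 and -0.0088, and 0 controls matched best to their own number. The adipose covariate gave 160 changed genes (58 higher, 102 lower), 125 of them at least 1.5-fold (45 higher, 80 lower), 28 named genes, and Pgr at 0.46 (adjusted p = 0.127). All 2209 genes kept their direction under it, with a median ratio of the log2 change of 1.04 and a median ratio of the SE of 1.40. Counting all 35556 probe sets, 529 fell at least 1.5-fold. Near the loci, the odds ratio was 0.630 with cyclic loess and 0.645 with robust shrinkage, both past p = 0.05 by Fisher exact test, against 0.731. Camera with an estimated correlation called 0 of 29 lists, where fry called 13, without the pan-epithelial, smooth muscle, macrophage, neutrophil and adipose lists (adjusted p from 0.0766 to 0.202) and with the luminal epithelium, transport and red blood cell lists (up to 0.0482). Calls of dim genes are limited by signal over background, which is unknown here.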

Other observations

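The lists were chosen before the values were seen, and Ptgs2 and Lif after. Signalling molecules of the uterus outside the groups described so far moved in both directions. Of 22 prostaglandin genes, 3 rose, 3 fell and 16 did not pass (3 higher and 7 lower adjusted over the list alone; median -0.09, adjusted p = 0.361 with camera, and 0.479 with an estimated correlation). The prostaglandin E2 receptor genes Ptger4 and Ptger2 fell by 0.88 (SE 0.12, adjusted p = 0.0060) and 0.83 (SE 0.16, adjusted p = 0.017), and the phospholipase gene Pla2g10, which releases fatty acids from membranes, fell by 1.14 (SE 0.21, adjusted p = 0.015). The carbonyl reductase gene Cbr2 rose by 1.60 (SE 0.16, adjusted p = 0.0015). Ptgs2, the inducible cyclooxygenase gene, had a log2 change of 2.32, and its dependence on single arrays was not looked at. The call of Ptger2 was lost without control replicate 2, 3 or 4 (adjusted p up to 0.0575) and that of Pla2g10 without control replicate 2 or 3 (up to 0.0530). Of 27 WNT pathway genes, 8 rose and 1 fell (9 and 3 adjusted over the list alone; median 0.10, mean 0.03, adjusted p = 0.105, and 0.467 with an estimated correlation). The WNT list passed without Foxa2-deleted replicate 3 (adjusted p = 0.0316) and with the dimmest 25% of genes left out (adjusted p = 0.0426). The ligand genes Wnt5a, Wnt7b and Wnt5b rose by 0.47 (SE 0.09), 0.57 (SE 0.12) and 0.21 (SE 0.04), with adjusted p of 0.016 to 0.021, and the R-spondin receptor gene Lgr4 fell by 0.43 (SE 0.07, adjusted p = 0.012). The call of Wnt5a was lost without control replicate 4 (adjusted p = 0.0539), that of Wnt7b without any 1 control or Foxa2-deleted replicate 1 (up to 0.0677), and that of Wnt5b without control replicate 2, 3 or 4 or Foxa2-deleted replicate 1 (up to 0.0692). Lif, the gland cytokine needed for implantation, did not pass. It had a log2 change of 0.12, with controls from 8.36 to 8.62 and deleted uteri at 7.99, 8.31, 9.77 and 8.18 on replicates 1 to 4.

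Of 18 immediate early genes, 3 fell and none rose, with the same numbers adjusted over the list alone (median -0.04, adjusted p = 0.179, and 0.698 with an estimated correlation; adjusted p = 0.0341 without control replicate 2). Atf3, Egr1 and Klf2 fell by 0.45 (SE 0.09), 0.60 (SE 0.15) and 0.41 (SE 0.09), with adjusted p of 0.018, 0.039 and 0.029. The call of Atf3 was lost without control replicate 2 (adjusted p = 0.0609), that of Egr1 without any 1 of 5 arrays (up to 0.0968) and that of Klf2 without any 1 of 6 (up to 0.0802). Of 20 interferon-stimulated genes only Ddx58, the viral RNA sensor RIG-I, passed, at -0.39 (SE 0.10, adjusted p = 0.043), and 0 passed adjusted over the list alone (median 0.10, adjusted p = 0.532, and 0.834 with an estimated correlation). The interferon list mean stood at 0.80 above controls on Foxa2-deleted replicate 3 and at -0.11, -0.06 and -0.05 on replicates 1, 2 and 4. Of 6 red blood cell genes measured, Car2, which encodes carbonic anhydrase 2 and sits in the transport list too, rose by 0.89 (SE 0.22, adjusted p = 0.038) and 5 did not pass, with 1 passing adjusted over the list alone (median 0.12, adjusted p = 0.0708, and 0.321 with an estimated correlation; adjusted p = 0.0360 without control replicate 1). Car2 lost its call without any 1 of 6 arrays (adjusted p up to 0.102), and Ddx58 also without any 1 of 6 (up to 0.111).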
